A study of Sus scrofa with 25 samples.

How the data were processed

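Muscle RNA from 25 pigs was measured, with 1 library per pig. The pigs were offspring of Polish Large White sows and Landrace boars, and their feed held vitamin D3 at 0, 5000 or 10000 IU/kg. Per the labels, RNA was extracted with the Total RNA Mini kit of A&A Biotechnology and libraries were made with the Lexogen QuantSeq FWD kit, which reads the 3' end of mRNA, so that counts do not scale with transcript length. The muscle sampled, the sex and the litter of each pig were not given in the sources used here.

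The deposited values were raw counts, that is whole numbers of reads per Ensembl pig gene, with no normalization by the authors found in them and 1 file per pig. The submitters' processing notes named FastQC, without a version. The aligner, the counting program, the genome build and the annotation release were not given in the sources used here. Each file ended with 5 summary lines under the names that htseq-count writes, and these lines stayed out of library sizes and tests. Among the reads in a file, 24.9% to 70.6% were assigned to genes, 16.3% to 38.1% lay outside annotated genes, 12.5% to 38.7% aligned to several places and 0.299% to 0.608% were ambiguous. The summary lines for unaligned and low-quality reads were 0 in the files, so these shares leave out such reads. The files also listed ERCC and SIRV spike-ins, which held 1 read in control replicate 23 and 0 in the other libraries, and these were not used. The files held 25880 pig gene identifiers. The file of D10000 replicate 27 lacked 1 of them, and 25879 were analysed. Symbols came from an Ensembl table of gene names, which gave one to 14857 identifiers. No coordinates were used.

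Total gene counts ran from 3310507 to 15177976 per library, with a mean of 8656600 ± 2970000 (SD, n = 25). Genes with low counts were removed with filterByExpr of edgeR 4.0.16 over the 3 diets (minimum count 10, minimum total 15), which left 10992 genes, 9666 of them with a symbol. Libraries were scaled by TMM. Counts were fitted with glmQLFit and glmQLFTest of edgeR (robust estimation) in R 4.3.3, with diet as the only term and all 25 libraries in 1 fit. Animal numbers were not shared between diets and litters were not in the labels, so no pairing or block was used. The 3 contrasts were 5000 IU/kg against control, 10000 IU/kg against control, and 10000 against 5000 IU/kg. A joint test covered both dose coefficients, and a dose trend was fitted per 5000 IU/kg. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes carry the standard error (SE) of the fit, with a prior count of 0.125. The common biological coefficient of variation was 0.669.

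Before the data were examined, the tests, the alternatives, the 22 gene lists and the rule for named genes were fixed. A list with at least 5 tested members was tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, and 21 lists could be tested. The list of Y-linked genes had 1 tested member and was left out. Adjusted p-values of lists cover the 21 lists within a contrast. Camera was repeated with an estimated correlation, and fry tested each list by itself. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the members of 1 list. List means are means of log2 CPM (counts scaled to library size) with a prior count of 2. The rule for named genes gave each gene past the threshold, the 4 members with the smallest p of up to 5 lists that passed camera in a contrast, and a fixed group (VDR, RXRA, CYP2R1, CYP24A1, CYP27B1, PDIA3, MSTN, MYH1, MYH2, MYH4 and MYH7). Of the genes picked by this rule 2 are not reported here and were not replaced by others. The 4 myosin heavy chain symbols matched no identifier and have no value here. Lists of liver and lung transcripts were written after ALB, APOA1 and SFTPC had been seen in the libraries, and before any test on them.

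Library measures were compared between diets with exact permutation tests of the difference of means (12870 or 24310 splits, two-sided) and, over the 3 diets, a permutation test with 1e+05 permutations. Pearson r of the relations across the 25 libraries was computed on values centred within diets, and rho on uncentred values. Both had 1e+05 permutations within diets. Pearson r within the sets of libraries by the APOC3 to ALB ratio was computed on uncentred values. Rates from pooled counts have exact Poisson intervals at 95%, and a count of 0 allows up to 3 counts of the total. Intervals of the APOC3 to ALB ratio come from the Clopper-Pearson method at 95%. The libraries have no molecular identifiers as far as the labels say, so intervals and floors cover counting error only. The correlation of the fold changes of both doses was set against 100 simulated data sets without a diet effect and against all 70 splits of the controls into 4 and 4. Results were set against 100 splits of the libraries into groups of 8, 8 and 9, the real one included.

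The pipeline was tested on simulated data with the same group sizes and 50 changed genes at each fold. Of these, 0% to 4% were called at a fold of 1.5 and 10% to 12% at a fold of 2. At a fold of 4, 62% to 72% were called, and at a fold of 8, 72% to 88%, with 2 or 3 unchanged genes called per comparison. A list shifted by 0.5 on the log2 scale was called by camera with either kind of correlation, and 0 of the other lists were. The simulated genes were drawn independently of each other, so this cannot show how either list test behaves with correlated genes. The simulated data also held no outlying library and no structure by the share of assigned reads, so the rates for genes may be lower in the real data. No pair of libraries held the same counts: among 300 pairs, the highest Pearson r of log2 CPM was 0.934.

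The alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter (at least 1 CPM in 8 libraries and a mean count of 20), non-robust estimation, voom with sample quality weights, 1 surrogate variable from sva 3.50.0, fits on only the diets compared, an adjusted p under 0.1, and leaving out each of the 25 libraries in turn. Alternatives chosen after seeing the data were leaving out 5 doubtful libraries, covariates for liver transcripts, adipocyte markers and the share of assigned reads, a term for 2 sets of libraries defined by the ratio of APOC3 to ALB counts, and the vitamin D list without genes of the liver list. The 5 libraries were D10000 replicate 27 and the 4 with the lowest share of assigned reads (D10000 replicates 2 and 7, D5000 replicates 11 and 18). No control library was left out, and control replicate 23, with the next lowest share (45.1%), was kept. For lists that follow the share, a smaller difference from the control under this setting is therefore partly built in. Figures were drawn with matplotlib 3.10.9.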

Results

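Transcript levels were measured in muscle of 25 pigs whose feed differed in vitamin D3 for 90 days from day 85 of life. The control group (8 pigs) had 0 IU/kg, the D5000 group (8 pigs) 5000 IU/kg and the D10000 group (9 pigs) 10000 IU/kg, and the pigs of a litter were divided over the diets. Replicates carry the animal numbers of the labels. Gene counts per library ran from 6403176 to 11222956 in the control, from 4328704 to 12203813 in D5000 and from 3310507 to 15177976 in D10000. The skeletal actin gene ACTA1 held 11.4% ± 5.74 (SD, n = 25) of the gene counts, the glycolytic gene GAPDH 3.35% ± 1.30 and the mitochondrially encoded COX3 2.20% ± 0.785. The 10 most abundant genes of a library together took 17.0% to 45.4% of its counts. Of 10992 genes tested, the typical log2 fold change had an SE of 0.43 at 5000 IU/kg against control and 0.42 in the other contrasts (medians over genes).

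The comparison of 5000 IU/kg with the control asked what the lower dose does to muscle transcripts. As a set, genes of fast-twitch contraction were lower and genes of vitamin D metabolism and signalling were higher than in the control, while 0 single genes passed the threshold. Of 100 splits of the libraries, the real one included, 96 gave at least 2 lists, so chance could not be excluded for this count. Of 14 fast-twitch genes tested, 12 were lower, with a median log2 fold change of -0.35 (camera adjusted p = 0.0356, and adjusted p = 0.91 with an estimated correlation). The mean of this list lay under the control mean in 5 of 8 libraries. Its members with the smallest p were MYLK2 (ENSSSCG00000007231), the kinase of skeletal myosin light chain, at a log2 fold change of -1.39 ± 0.66 (SE, n = 8 per diet), and ATP2A1 (ENSSSCG00000007805), the calcium pump of fast fibres, at -1.40 ± 0.68. The calcium buffer PVALB (ENSSSCG00000000138) stood at -1.11 ± 0.57 and the fast troponin TNNI2 (ENSSSCG00000033260) at -0.94 ± 0.55. Of 17 tested genes of vitamin D metabolism and signalling, 14 were higher, with a median of 0.38 (camera adjusted p = 0.0356, and adjusted p = 0.91 with an estimated correlation), and the list mean lay above the control mean in 7 of 8 libraries. SMARCA4 (ENSSSCG00000013629), a chromatin remodeller, stood at 0.43 ± 0.25, the secreted phosphoprotein SPP1 (ENSSSCG00000009216) at 1.5 ± 1.01 (0.72 without D5000 replicate 11) and the coactivator NCOA3 (ENSSSCG00000007458) at 0.73 ± 0.62. CYP27A1 and GC are also in the list of liver transcripts, and without both the vitamin D list had a median of 0.33 and an adjusted p of 0.0625. Libraries of D5000 had a share of reads assigned to genes of 51.8% ± 12.6 (SD, n = 8) against 58.4% ± 8.76 (SD, n = 8) in the control, and the vitamin D list was higher in libraries with a low share. With the share as a covariate the fast-twitch list had a median of -0.09 (adjusted p = 0.347) and the vitamin D list 0.15 (adjusted p = 0.382). With liver transcripts as a covariate the medians were -0.10 (adjusted p = 0.058) and 0.03 (adjusted p = 0.484). Both covariates were chosen after seeing the data, and the liver transcripts share CYP27A1 and GC with the vitamin D list.

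With edgeR, 0 of 10992 genes passed at 5000 IU/kg (smallest adjusted p = 0.999). At an unadjusted p under 0.05 there were 371 genes, 236 higher and 135 lower, where 549.6 would fall by chance, and DESeq2 and voom also called 0 genes (510 and 737 at an unadjusted p under 0.05). Adjusted over the list alone, 1 extracellular matrix gene and 1 immune cell gene passed, and both are named here after their values were seen. These were the matricellular growth factor CCN2 (ENSSSCG00000004192) at 1.31 ± 0.37 (adjusted p = 0.0394 in edgeR) and the granzyme GZMA (ENSSSCG00000016903) at 2.73 ± 0.73 (adjusted p = 0.023 in edgeR). The other 19 lists had 0 genes adjusted over the list alone. With fry, 0 of 21 lists passed in any contrast. Both list calls depended on single libraries. The fast-twitch contractile genes no longer passed without control replicate 9 (adjusted p = 0.106), 10 (0.0713), 14 (0.132) or 16 (0.0642), or without D5000 replicate 18 (0.154), 24 (0.133) or 29 (0.0777). The vitamin D metabolism and signalling genes no longer passed without control replicate 10 (adjusted p = 0.0709) or 16 (0.0642), or without D5000 replicate 11 (0.0947), 18 (0.124) or 29 (0.0546). Without 1 of these libraries the list median ran from -0.36 to -0.17 for fast-twitch and from 0.25 to 0.39 for vitamin D. Of 8 other settings, 5 ended the vitamin D call and 4 the fast-twitch call. With 1 surrogate variable the vitamin D list had a median of 0.22 (adjusted p = 0.258). Without the 5 doubtful libraries, none of them a control, the medians were 0.14 for vitamin D (adjusted p = 0.386) and -0.15 for fast-twitch (adjusted p = 0.101).

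The comparison of 10000 IU/kg with the control asked the same of the higher dose. Genes of mitochondrial energy production and of muscle contraction were lower as sets, and markers of fat cells and of extracellular matrix were higher as sets, with 0 single genes past the threshold. None of these calls held with an estimated correlation, and those of contraction, fat cells and extracellular matrix ended without D10000 replicate 27. In all 11 lists passed, and 12 of 100 splits of the libraries, the real one included, gave at least as many. Of 59 tested nuclear genes of oxidative phosphorylation, 54 were lower, with a median log2 fold change of -0.31 (camera adjusted p = 2.33e-11, and adjusted p = 0.33 with an estimated correlation). The list mean lay under the control mean in 7 of 9 libraries. UQCR11 (ENSSSCG00000013436), a subunit of complex III, stood at -0.74 ± 0.34 (SE, n = 9 against 8), CYC1 (ENSSSCG00000031918), cytochrome c1, at -0.54 ± 0.29 and NDUFS3 (ENSSSCG00000032081), a subunit of complex I, at -0.48 ± 0.27. COX6A1 (ENSSSCG00000039265), a subunit of complex IV that skeletal muscle largely replaces by COX6A2, stood at 0.91 ± 0.45 with all libraries and at -0.14 ± 0.27 without D10000 replicate 27. All 13 genes encoded in mitochondrial DNA were lower, with a median of -0.38 (camera adjusted p = 0.000391, and adjusted p = 0.418 with an estimated correlation), and 8 of 9 libraries lay under the control mean. ND4 (ENSSSCG00000018087) stood at -0.59 ± 0.34, CYTB (ENSSSCG00000018094) at -0.60 ± 0.37, ND2 (ENSSSCG00000018069) at -0.64 ± 0.42 and ATP6 (ENSSSCG00000018081) at -0.57 ± 0.38. Libraries of D10000 had a share of reads assigned to genes of 53.5% ± 13.1 (SD, n = 9), against 58.4% ± 8.76 (SD, n = 8) in the control, and the oxidative phosphorylation list was lower in libraries with a low share. Neither call ended when any 1 library was left out. With the share as a covariate, also chosen after seeing the data, both lists still passed camera with the preset correlation. The median was -0.16 for oxidative phosphorylation (adjusted p = 6.39e-06) and -0.32 for the mitochondrially encoded genes (adjusted p = 0.0037). Without the 5 doubtful libraries, an alternative chosen after seeing the data, the oxidative phosphorylation list had a median of -0.11 (adjusted p = 0.114) and the mitochondrially encoded genes -0.24 (adjusted p = 0.0596). That alternative took low shares of assigned reads out of the vitamin D3 diets only, so part of the smaller difference is built in for oxidative phosphorylation.

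With all 25 libraries, contractile genes were lower in both fibre classes at 10000 IU/kg. Of 14 fast-twitch genes 13 were lower, with a median of -0.41 (camera adjusted p = 7.02e-06, and adjusted p = 0.33 with an estimated correlation), with 6 of 9 libraries under the control mean. The fast troponins TNNC2 (ENSSSCG00000007424), TNNI2 and TNNT3 (ENSSSCG00000031903) stood at -0.78 ± 0.45, -0.84 ± 0.53 and -0.73 ± 0.46, and PVALB at -0.80 ± 0.55. Of 13 slow-twitch genes 11 were lower, with a median of -0.42 (camera adjusted p = 0.00325, and adjusted p = 0.502 with an estimated correlation), with 5 of 9 libraries under the control mean. Calcium handling genes were lower in 24 of 39 (median -0.16, camera adjusted p = 0.0107, and adjusted p = 0.502 with an estimated correlation), with 4 of 9 libraries under the control mean. D10000 replicate 27 had the lowest mean of the fast-twitch list among the 25 libraries (6.36 log2 CPM, against a D10000 mean of 9.66 ± 1.34, SD, n = 9). Without D10000 replicate 27 none of these 3 lists passed: the median was -0.25 for fast-twitch (adjusted p = 0.0519), -0.26 for slow-twitch (0.272) and -0.04 for calcium handling (0.844). The slow-twitch call also ended without control replicate 16 (median -0.10, adjusted p = 0.0816) and the calcium handling call without control replicate 14 (median -0.04, adjusted p = 0.12). With the share of assigned reads as a covariate, the fast-twitch list still passed camera with the preset correlation (median -0.32, adjusted p = 0.00032). The slow-twitch list (adjusted p = 0.148) and the calcium handling list (0.0856) did not. With 1 surrogate variable the calcium handling call ended (median -0.19, adjusted p = 0.0546), and the fast-twitch and slow-twitch lists still passed. Leaving out the 5 doubtful libraries turned the direction of 2 of these lists, with medians of 0.02 for slow-twitch (7 of 13 higher, adjusted p = 0.15) and 0.06 for calcium handling (adjusted p = 0.384), and left fast-twitch at -0.16 (adjusted p = 0.507).

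Markers of fat cells and of lipid synthesis were higher in 26 of 27 genes at 10000 IU/kg, with a median log2 fold change of 0.86 (camera adjusted p = 5.63e-05, and adjusted p = 0.33 with an estimated correlation). The stearoyl-CoA desaturase SCD (ENSSSCG00000010554) stood at 2.86 ± 0.82, the fatty acid synthase FASN (ENSSSCG00000029944) at 2.47 ± 0.73, the ATP citrate lyase ACLY (ENSSSCG00000017421) at 3.21 ± 1.01 and the acetyl-CoA carboxylase ACACA (ENSSSCG00000017694) at 2.29 ± 0.74. These 4 stood, without D10000 replicate 27, at 0.48 ± 0.38, 0.25 ± 0.30, 0.47 ± 0.52 and 0.41 ± 0.41. Adjusted over the list alone, 8 adipocyte genes passed in edgeR with all libraries and 0 without that replicate (smallest adjusted p = 0.38). Markers of fibroblasts and extracellular matrix were higher in 32 of 34 genes, with a median of 0.52 (camera adjusted p = 6.08e-05, and adjusted p = 0.33 with an estimated correlation), and 0 passed adjusted over the list alone. The gelatinase MMP2 (ENSSSCG00000002829) stood at 1.44 ± 0.54, the collagen COL6A1 (ENSSSCG00000022506) at 1.53 ± 0.58, CCN2 at 0.90 ± 0.36 and the proteoglycan FMOD (ENSSSCG00000015270) at 1.31 ± 0.53. Leaving out D10000 replicate 27 gave 0.05 ± 0.34, 0.37 ± 0.39, 0.92 ± 0.36 and -0.08 ± 0.33. Of the 25 libraries, D10000 replicate 27 had the highest mean of both lists. The hormone gene ADIPOQ had 15866 counts there and 5 to 538 in the other 24 libraries, and TRARG1 had 60164 counts against 2 to 209. ACTA1 stood at 7808 CPM there and at 21480 to 315500 CPM elsewhere. The mean of the adipocyte list lay above the control mean in 5 of 9 libraries and that of the extracellular matrix list in 6 of 9. Without D10000 replicate 27 the adipocyte and lipogenesis markers had a median of 0.25 (adjusted p = 0.172) and the extracellular matrix markers one of 0.26 (adjusted p = 0.293). Leaving out the 5 doubtful libraries turned the adipocyte median to -0.02 (13 genes higher, adjusted p = 0.804), with 0.18 for extracellular matrix (adjusted p = 0.322).

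Genes of fatty acid uptake and oxidation were lower in 26 of 40 (median -0.17, camera adjusted p = 0.00389, and adjusted p = 0.33 with an estimated correlation), with 8 of 9 libraries under the control mean. The call ended without control replicate 16 (median -0.08, adjusted p = 0.0506). Immediate-early and heat-shock genes were higher in 24 of 31 (median 0.24, camera adjusted p = 0.0107, and adjusted p = 0.33 with an estimated correlation), and this ended without D10000 replicate 13 (adjusted p = 0.0851), 20 (0.0721) or 30 (0.05), at medians of 0.13 to 0.21. Glycolysis and glycogen genes were lower in 21 of 33 (median -0.09, camera adjusted p = 0.0284, and adjusted p = 0.621 with an estimated correlation). This call ended without D10000 replicate 2 (adjusted p = 0.0562), 7 (0.0556), 13 (0.0851) or 27 (0.908), or without control replicate 9 (0.129), 10 (0.14) or 14 (0.307), at medians of -0.10 to 0.04. Genes of protein degradation and atrophy were lower in 23 of 42 (median -0.03, camera adjusted p = 0.0123, and adjusted p = 0.502 with an estimated correlation), against a median of 0.07 over all tested genes, and RLE scaling turned the sign of the list median. The 5 doubtful libraries left out gave glycolysis a median of 0.09 (adjusted p = 0.101), the other way. The share of assigned reads as a covariate also turned it, to 0.07 (adjusted p = 0.392). In all, the glycolysis call ended under 6 of 8 other settings, among them 1 surrogate variable (median -0.12, adjusted p = 0.0587). The protein degradation call ended without D10000 replicate 2 (adjusted p = 0.0797), 7 (0.0556) or 27 (0.272), or without control replicate 3 (0.0556) or 16 (0.0685), at medians of -0.02 to 0.06. The list mean lay above the control mean in 5 of 9 libraries for immediate-early and heat-shock genes, and under it in 5 of 9 for glycolysis and in 6 of 9 for protein degradation.

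The other 10 lists did not pass at 10000 IU/kg. Their medians were 0.10 for vitamin D metabolism and signalling, 0.24 for endothelial markers, 0.11 for smooth muscle and pericyte markers, 0.08 for immune cell markers and 0.11 for blood cell and haemoglobin genes. They were 0.00 for Schwann cell and nerve markers, 0.06 for myogenesis and growth, 0.19 for circadian clock genes, 0.15 for interferon-stimulated genes and -0.07 for cytosolic ribosomal proteins. The camera direction was down for the blood cell, the Schwann cell and the myogenesis lists, opposite to their medians, and the mean of the Schwann cell list was -0.11. At 5000 IU/kg the median and the mean differed in sign for the Schwann cell list (0.03 and -0.16), the endothelial list (-0.04 and 0.09) and the myogenesis list (-0.03 and 0.06). The medians of all 21 lists at both doses are plotted.

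**Figure D1:**
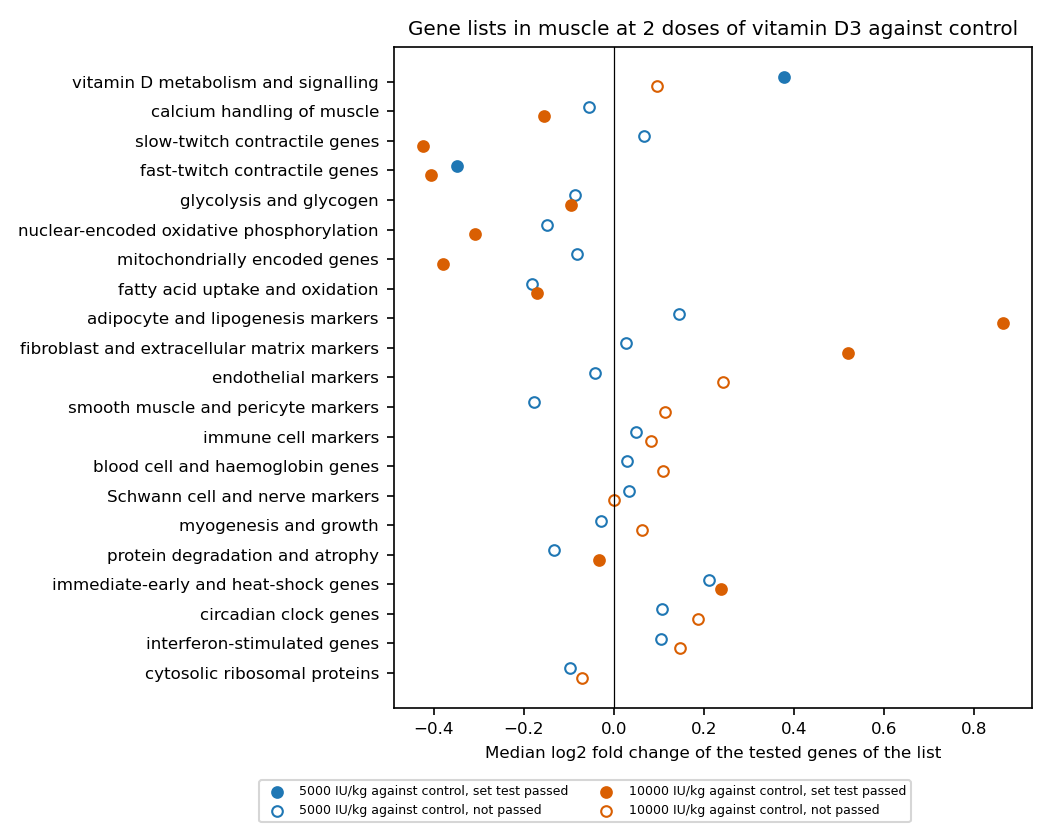
Median log2 fold change against control of the tested genes of each of 21 gene lists, for 5000 IU/kg (blue) and 10000 IU/kg (orange). Filled points passed camera with a preset correlation of 0.01, and the adipocyte and lipogenesis list at 10000 IU/kg lies farthest to the right, at 0.86.

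With edgeR, 0 of 10992 genes passed at 10000 IU/kg against control (smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 263 genes, 231 higher and 32 lower, where 549.6 would fall by chance. DESeq2 and voom called 0 genes (339 and 289 at an unadjusted p under 0.05). Without D10000 replicate 27, 5 lists passed, among them the cytosolic ribosomal proteins (median -0.14, adjusted p = 0.0257). Without the 5 doubtful libraries 2 lists passed, those of fatty acid uptake and oxidation and of immediate-early and heat-shock genes. The list means per library of 4 lists are plotted, with D10000 replicate 27 marked.

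**Figure D2:**
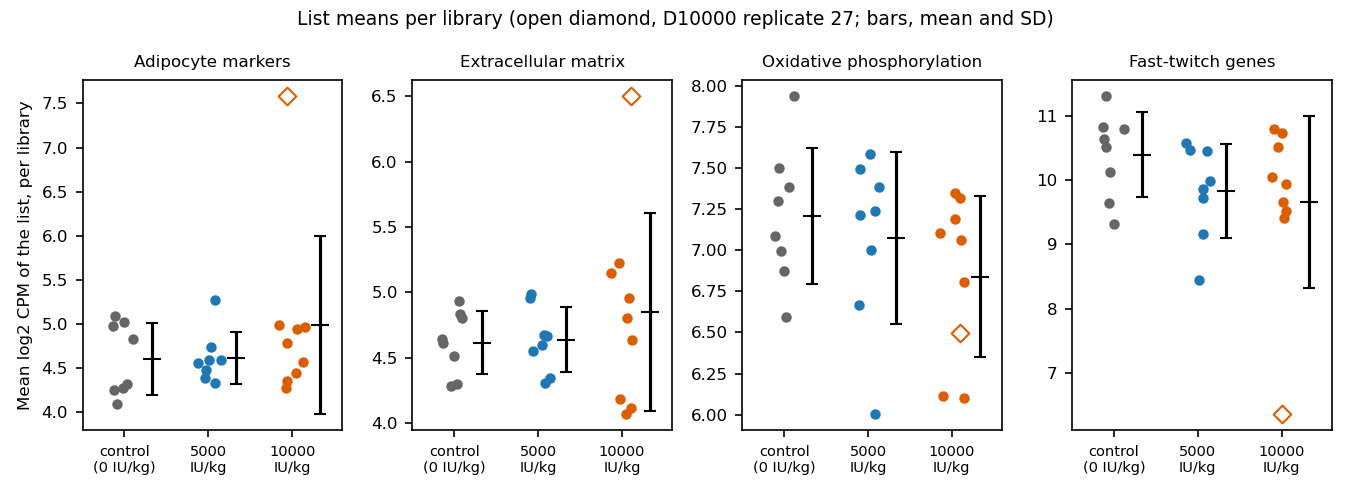
Mean log2 CPM of 4 gene lists in each library by diet (8, 8 and 9 libraries), with the mean and SD of each diet as bars. The open diamond is D10000 replicate 27, at 7.59 in the adipocyte list against a D10000 mean of 4.99, and at 6.36 in the fast-twitch list against 9.66.

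The comparison of 10000 with 5000 IU/kg tested whether the doses differ. Mitochondrial and slow-twitch genes were lower at the higher dose, and extracellular matrix and adipocyte markers were higher, each as a set. For the 5 lists that passed camera, the adjusted p was 0.773 with an estimated correlation. At least 5 lists were reached by 63 of 100 splits of the libraries, the real one included. Of 59 oxidative phosphorylation genes 46 were lower (median -0.21, camera adjusted p = 4.67e-05), with 5 of 9 libraries under the D5000 mean. ATP5MC1 (ENSSSCG00000017544) of the ATP synthase stood at -0.71 ± 0.33, NDUFA2 (ENSSSCG00000014371) of complex I at -0.63 ± 0.31 and COX7A2 (ENSSSCG00000004480) at -0.62 ± 0.32. All 13 mitochondrially encoded genes were lower (median -0.33, camera adjusted p = 0.016), with 7 of 9 libraries under the D5000 mean. ND5 (ENSSSCG00000018091) stood at -0.53 ± 0.33, ND6 (ENSSSCG00000018092) at -0.47 ± 0.34, ND4L (ENSSSCG00000018086) at -0.41 ± 0.31 and ND1 (ENSSSCG00000018065) at -0.45 ± 0.37. Of 13 slow-twitch genes 11 were lower (median -0.53, camera adjusted p = 0.00179), with 6 of 9 libraries under the D5000 mean. The slow troponins TNNC1 (ENSSSCG00000011441), TNNI1 (ENSSSCG00000024061) and TNNT1 (ENSSSCG00000025353) stood at -0.94 ± 0.55, -0.91 ± 0.57 and -0.81 ± 0.57, and the slow myosin light chain MYL2 (ENSSSCG00000039710) at -0.77 ± 0.56. Without D5000 replicate 24 the 3 troponins stood at -0.20, -0.06 and -0.08. Extracellular matrix markers were higher in 29 of 34 (median 0.49, camera adjusted p = 0.016), with 6 of 9 libraries above the D5000 mean. MMP2 stood at 1.51 ± 0.54, the fibroblast protease FAP (ENSSSCG00000015896) at 1.26 ± 0.47, FMOD at 1.31 ± 0.54 and the proteoglycan OGN (ENSSSCG00000034607) at 1.49 ± 0.63. The 4 values were, without D10000 replicate 27, 0.11 ± 0.34, 0.79 ± 0.45, -0.09 ± 0.33 and -0.08 ± 0.36. Adipocyte markers were higher in 22 of 27 (median 1.13, camera adjusted p = 0.0297), with 5 of 9 libraries above the D5000 mean, and 7 passed adjusted over the list alone (0 without D10000 replicate 27). FASN stood at 2.38 ± 0.73, the triglyceride lipases PNPLA2 (ENSSSCG00000012841) and LIPE (ENSSSCG00000003018) at 2.04 ± 0.68 and 2.87 ± 0.98, and ADIPOQ (ENSSSCG00000039103) at 3.06 ± 1.07 (3.98 without D5000 replicate 25). Leaving out D10000 replicate 27, the 4 values were 0.14 ± 0.30, 0.70 ± 0.45, 0.18 ± 0.49 and 0.45 ± 0.64.

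These calls also moved with single libraries. Without D10000 replicate 27 the adipocyte and lipogenesis markers had a median of -0.02 and the fibroblast and extracellular matrix markers one of 0.06 (adjusted p = 0.9 for each), and the slow-twitch list had a median of -0.40 (adjusted p = 0.236). With liver transcripts as a covariate the adipocyte list had a median of 0.51 (adjusted p = 0.0517) and the extracellular matrix list 0.28 (adjusted p = 0.0689), and with 1 surrogate variable 0.30 and 0.18 (adjusted p = 0.221 for each). Without D10000 replicate 2, 0 lists passed, with adjusted p = 0.0569 for the oxidative phosphorylation (median -0.13), slow-twitch (-0.40), adipocyte (1.26) and extracellular matrix (0.52) lists and 0.0737 for the mitochondrially encoded genes (-0.25). The adipocyte call ended as well without D5000 replicate 5 (adjusted p = 0.119), 15 (0.0628) or 29 (0.0985) and without D10000 replicate 7 (0.111) or 21 (0.0697). Without D10000 replicate 2 or any 1 of these 5 libraries the adipocyte median was 1.05 to 1.26, so these calls ended at a similar fold. The extracellular matrix call ended without D5000 replicate 5 (median 0.39, adjusted p = 0.111) and the slow-twitch call without D5000 replicate 24 (median -0.08, adjusted p = 0.119). The call of the mitochondrially encoded genes ended without D5000 replicate 15 (adjusted p = 0.238), 24 (0.0747) or 25 (0.262) and without D10000 replicate 7 (0.0973) or 21 (0.0636), at medians of -0.32 to -0.15. Apart from the estimated correlation and fry, 8 other settings were run. Of these, 0 ended the oxidative phosphorylation call and 0 that of the mitochondrially encoded genes. The slow-twitch call ended under 2, the adipocyte call under 4 and the extracellular matrix call under 4. With edgeR, 0 of 10992 genes passed between the doses (smallest adjusted p = 0.999), with 323 at an unadjusted p under 0.05, of which 232 were higher and 91 lower. DESeq2 called 0 genes (393 at an unadjusted p under 0.05). Voom with quality weights called 1 gene, GNAI1, a G protein subunit named here because it was that gene, at a log2 fold change of 3.85 (adjusted p = 0.0498 in limma, 459 genes at an unadjusted p under 0.05).

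A joint test over the 3 diets asked whether any diet differed, and a linear trend whether transcripts followed the dose. The trend gave the same 11 lists past camera as 10000 IU/kg against control. With 3 evenly spaced doses and groups of similar size, the slope rests almost wholly on the D10000 and control libraries. The match was therefore built in and is no separate sign of a dose response. At 5000 IU/kg the slow-twitch list, for one, had a median of 0.07 against control, with 8 of 13 genes higher. Per 5000 IU/kg the median slope on the log2 scale was -0.16 for oxidative phosphorylation (54 of 59 lower, adjusted p = 8.78e-12, and 0.341 with an estimated correlation) and -0.19 for mitochondrially encoded genes (13 of 13 lower, adjusted p = 0.000243, and 0.383 with an estimated correlation). It was -0.20 for fast-twitch genes (13 of 14 lower, adjusted p = 7.05e-06, estimated 0.341) and -0.22 for slow-twitch genes (11 of 13 lower, adjusted p = 0.00188, estimated 0.512). It was 0.45 for adipocyte markers (26 of 27 higher, adjusted p = 3.75e-05, estimated 0.341, 11 genes adjusted over the list alone and 0 without D10000 replicate 27) and 0.26 for extracellular matrix markers (32 of 34 higher, adjusted p = 4.02e-05, estimated 0.341). The other 5 were fatty acid uptake and oxidation, calcium handling, protein degradation, immediate-early and glycolysis genes (adjusted p = 0.00353, 0.00979, 0.0125, 0.0153 and 0.0229). With an estimated correlation their adjusted p was 0.341, 0.511, 0.483, 0.341 and 0.593 in that order. Left out singly, 0, 2, 4, 5 and 6 of the 25 libraries ended the call, in the same order. Of 8 other settings, 0, 4, 3, 0 and 5 ended it. Leaving out D10000 replicate 27 ended 7 of the 11 trend calls. The slope was then 0.13 for adipocyte (adjusted p = 0.183) and 0.13 for extracellular matrix markers (0.297), -0.12 for fast-twitch (0.058), -0.13 for slow-twitch (0.277), -0.02 for calcium handling (0.837), -0.02 for glycolysis (0.908) and -0.01 for protein degradation genes (0.284). The 5 lists that passed were then 4 of the 11 and the cytosolic ribosomal proteins (adjusted p = 0.0258). Leaving out the 5 doubtful libraries ended 9 of the 11 calls, those of oxidative phosphorylation (slope -0.05, adjusted p = 0.196) and mitochondrially encoded genes (-0.11, adjusted p = 0.0961) among them, and turned the slopes of slow-twitch (0.03), calcium handling (0.03), glycolysis (0.04) and adipocyte genes (-0.01). By edgeR 0 genes passed for the trend (smallest adjusted p = 0.999, 291 genes at an unadjusted p under 0.05) and 0 over the 3 diets (smallest adjusted p = 0.911, 292 genes). DESeq2 called 0 genes for both (326 and 380 at an unadjusted p under 0.05), as did voom (255 and 454). Non-robust estimation called 2 genes over the 3 diets, the aldolase ALDOC and the glucose transport regulator TRARG1 (adjusted p = 0.034 for each), both named here because they were those genes. TRARG1 stood at 3643 CPM in D10000 replicate 27 and at 0.233 to 22.8 CPM in the other libraries.

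Genes of vitamin D action itself were near the limit of detection, or had fold changes whose intervals spanned 0. VDR (ENSSSCG00000020864), the vitamin D receptor, had 106 counts in 13 of 25 libraries, too few for the gene test. Its level was 0.347 ± 0.437 CPM (SD, n = 8) in the control, 0.347 ± 0.468 (n = 8) in D5000 and 0.497 ± 0.879 (n = 9) in D10000. Exact permutation p-values, two-sided, were 1 for D5000 against control, 0.719 for D10000 against control and 0.72 between doses (adjusted p = 1 for each over the 3 contrasts). CYP24A1 (ENSSSCG00000007486), which inactivates vitamin D and is induced through the receptor, had 0 counts in all 25 libraries, which allows up to 0.0142 CPM over the pooled counts. CYP27B1 (ENSSSCG00000028637), which makes the active hormone, had 11 counts in 3 libraries, a pooled rate of 0.052 CPM (95% exact Poisson interval 0.026 to 0.093). A difference in these 2 genes was not detectable at this depth. RXRA (ENSSSCG00000038220), the partner of the receptor, stood at a log2 fold change of 0.02 ± 0.23 at 5000 IU/kg and 0.05 ± 0.22 at 10000 IU/kg. The hydroxylase CYP2R1 (ENSSSCG00000013389) stood at 0.94 ± 0.88 and 1.04 ± 0.86 (1.60 and 1.71 without control replicate 9), and the disulfide isomerase PDIA3 (ENSSSCG00000004700), which has been described as a membrane receptor of vitamin D, at 0.33 ± 0.36 and 0.10 ± 0.35. MSTN (ENSSSCG00000016047), a brake on muscle growth, stood at -0.54 ± 0.64 and 0.11 ± 0.62. Between doses the 4 values were 0.03 ± 0.22 for RXRA, 0.10 ± 0.84 for CYP2R1, -0.23 ± 0.34 for PDIA3 and 0.66 ± 0.63 for MSTN.

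The fold changes of both doses against the same control were compared across genes, to see whether the doses acted alike. Pearson r across 10992 genes was 0.467 (jackknife SE over the 25 libraries 0.221), with a covariance of 0.123 (SE 0.084), and 70.1% of genes had the same sign (SE 9.72). Genes are not independent replicates, and a shared control alone gave a mean r of 0.517 (0.484 to 0.539), a covariance of 0.157 (0.144 to 0.167) and the same sign in 67.2% of genes (66.2% to 68.3%) in 100 simulated data sets without a diet effect. With the 8 controls split 4 and 4, so that the contrasts shared no library, r had a mean of 0.0871 (-0.117 to 0.175 over 70 splits) the covariance one of 0.0325 and the same-sign share one of 55.5%. The observed r and covariance lay under and the same-sign share above the simulated range, each by less than its SE, so no shared effect of the doses was shown.

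Library makeup was compared to see whether cell types or depth differed between diets. None of 10 measures passed the test over the 3 diets (permutation test, smallest p = 0.408, adjusted p = 0.982 for each). The mean of the adipocyte markers was 4.61 ± 0.408 log2 CPM (SD, n = 8) in the control, 4.62 ± 0.294 (n = 8) in D5000 and 4.99 ± 1.01 (n = 9) in D10000. The extracellular matrix markers stood at 4.61 ± 0.241, 4.64 ± 0.249 and 4.85 ± 0.760 in the same order. Transcripts typical of liver were found in all libraries, among them ALB, the serum albumin gene, with 11361 to 103105 counts. The 52 tested genes of the liver list took 0.706% to 6.82% of the counts of a library. Their mean was 7.05 ± 0.751 log2 CPM in the control, 7.54 ± 0.659 in D5000 and 7.14 ± 0.881 in D10000 (permutation p = 0.419 over the 3 diets, adjusted p = 0.597 over 4 added measures). The lung list, 9 genes, stood at 1.12 ± 1.98, 0.445 ± 1.77 and 0.213 ± 1.88 log2 CPM (permutation p = 0.597).

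Several gene groups followed the share of reads assigned to genes, which ran from 24.9% to 70.6% over the 25 libraries. Across the 25 libraries 5 relations were computed, with r centred within diets and rho not centred. The oxidative phosphorylation list rose with the share (r = 0.892, permutation p = 1e-05, the smallest 1e+05 permutations can give, adjusted p = 2.5e-05, and rho = 0.743, permutation p = 2e-05, adjusted p = 3.33e-05). The vitamin D list fell with it (r = -0.801, permutation p = 3e-05, adjusted p = 5e-05; rho = -0.767, permutation p = 3e-05, adjusted p = 3.75e-05), as did the liver transcripts (r = -0.740, permutation p = 5e-05, adjusted p = 6.25e-05; rho = -0.775, permutation p = 2e-05, adjusted p = 3.33e-05). Without D5000 replicate 18 and D10000 replicate 2, the libraries farthest from the median share, r was 0.835, -0.790 and -0.758. The vitamin D list had r = 0.819 with the liver transcripts, of which a part is built in, since CYP27A1 and GC are in both lists. Without these 2 genes r was 0.662 (permutation p = 0.00088, adjusted p = 0.00088; rho = 0.619, permutation p = 0.00243, adjusted p = 0.00243) and with the share of assigned reads -0.756 (permutation p = 0.00016, adjusted p = 0.00032; rho = -0.648, permutation p = 0.00089, adjusted p = 0.00178), adjusted over these 2 relations. The oxidative phosphorylation list fell with the liver transcripts (r = -0.596, permutation p = 0.00289, adjusted p = 0.00289; rho = -0.481, permutation p = 0.0101, adjusted p = 0.0101). Without D10000 replicates 27 and 7, the farthest from the median of the liver transcripts, r with these was 0.592 for the vitamin D list without the 2 shared genes and -0.667 for oxidative phosphorylation.

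The libraries also fell into a pair of sets by the ratio of APOC3 to ALB counts, both liver genes, and the labels give no batch. The ratio was 0.0944 to 0.261 in 7 libraries (2 control, 2 D5000, 3 D10000, animal numbers 23 to 30 without 25) and 0.00992 to 0.05 in 18 (6 of each diet). Within these sets r was computed without centring by diet. In the 18 libraries, r with the share of assigned reads was 0.918 for oxidative phosphorylation, -0.836 for the vitamin D list and -0.913 for liver transcripts. In the 7 libraries it was 0.539, -0.503 and -0.243. The vitamin D list without the 2 shared genes had r = 0.845 and 0.503 with the liver transcripts in the 18 and the 7 libraries. The relation of oxidative phosphorylation with liver transcripts did not hold within both, at r = -0.871 in the 18 libraries and 0.533 in the 7.

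**Figure D3:**
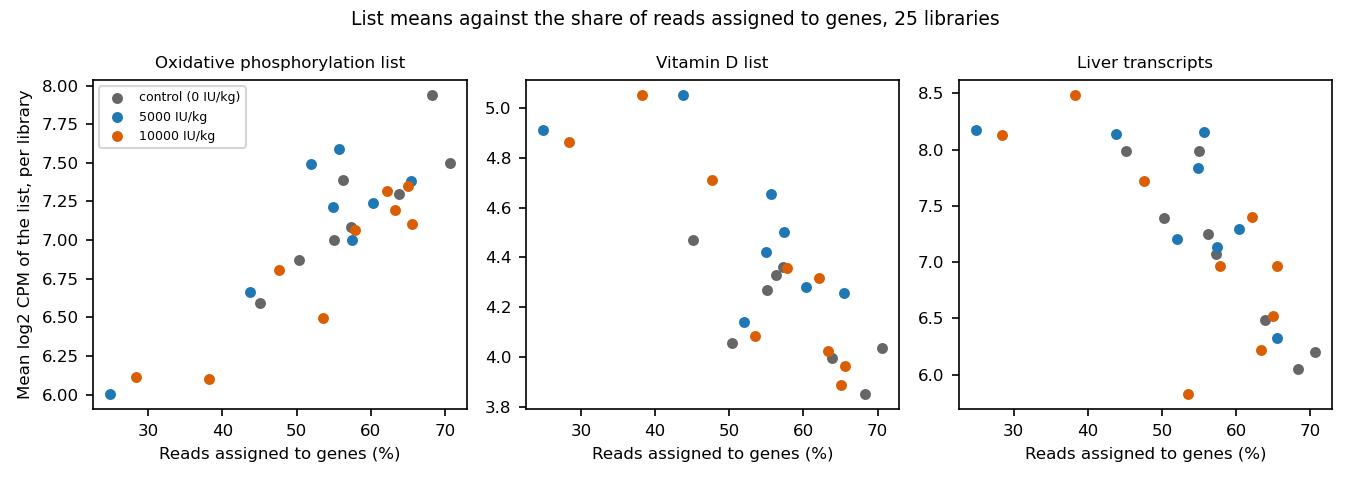
Mean log2 CPM of the oxidative phosphorylation list, the vitamin D list and the liver transcripts in each of 25 libraries, against the percent of reads assigned to genes, coloured by diet. Within diets, r was 0.892, -0.801 and -0.740.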

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

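The tests on D10000 replicate 27, on the share of assigned reads, on liver transcripts as a covariate and on the ratio of APOC3 to ALB counts were chosen after their results had been seen, while the diet test of the oxidative phosphorylation list and the test of the vitamin D list without liver genes were set down before theirs.

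In each diet, a library was singled out where its distance to the nearest other library was a large part of the whole range of that diet (Dixon's ratio at the 95% level). Of 216 groups tested (72 measures in 3 diets), 30 gave such a library. Of these groups 123 were of genes named for a small p, often through D10000 replicate 27, so their 16 flags cannot be held against chance. The other 93 groups (31 measures that no p-value picked) gave 14, where chance gives about 1 in 20 groups, and 8 of the 14 were D10000 replicate 27. D10000 replicate 27 accounted for 19 of the 30, and its ratios follow. It was highest for the adipocyte and lipogenesis markers (7.59 log2 CPM, ratio 0.783), the fibroblast and extracellular matrix markers (6.50, ratio 0.524) and the smooth muscle and pericyte markers (5.51, ratio 0.517). It was also highest for SCD (12.66, ratio 0.655), FASN (11.89, ratio 0.682), ACACA (8.72, ratio 0.509), LIPE (10.83, ratio 0.692) and COX6A1 (7.99, ratio 0.79). The same held for MMP2 (7.06, ratio 0.7), FMOD (7.33, ratio 0.667) and OGN (9.87, ratio 0.621). It was lowest for the lists of calcium handling of muscle (4.01, ratio 0.705), fast-twitch contractile genes (6.36, ratio 0.687), glycolysis and glycogen (6.04, ratio 0.574) and myogenesis and growth (2.52, ratio 0.563). It was lowest as well for TNNC2 (8.22, ratio 0.673), TNNT3 (8.67, ratio 0.649), MSTN (-1.75, ratio 0.618) and ND4L (6.35, ratio 0.5).

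The other 11 were spread over 9 libraries. D5000 replicate 24 was lowest for MSTN (-1.42 log2 CPM, ratio 0.561) and highest for slow-twitch contractile genes (9.02, ratio 0.532). D5000 replicate 6 was highest for COX7A2 (6.88, ratio 0.58). D5000 replicate 18 was lowest for COL6A1 (2.71, ratio 0.623) and for the Schwann cell and nerve markers (2.15, ratio 0.562). FMOD was highest in control replicate 28 (4.64, ratio 0.593) and lowest in D5000 replicate 15 (2.16, ratio 0.561). ND2 was highest in D10000 replicate 30 (14.03, ratio 0.496). D5000 replicate 25 was highest for the adipocyte and lipogenesis markers (5.27, ratio 0.566), D10000 replicate 21 for blood cell and haemoglobin genes (4.96, ratio 0.552) and D5000 replicate 5 for immediate-early and heat-shock genes (6.91, ratio 0.561).

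The higher adipocyte and extracellular matrix lists at 10000 IU/kg rested on D10000 replicate 27, since without it the adipocyte list had an adjusted p of 0.172 (from 5.84e-06 to 0.172 over the 25 libraries left out in turn, and 4.41e-05 to 0.804 over 8 other settings). A lower share of muscle RNA alone would raise the markers of other cell types alike. In this library the adipocyte list lay 9.19 SD and the extracellular matrix list 5.82 SD above the mean of the other 24. The smooth muscle, endothelial and immune cell lists lay 3.6, 3.3 and 2.2 SD above theirs. The blood cell list lay -1.1 SD and the Schwann cell and nerve list -1.49 SD from theirs. The latter was written with genes that muscle fibres also express, such as CHRNA1 and MUSK. It can fall with muscle RNA, so its value cannot decide. The adipocyte list rose by 2.96 log2 CPM (SD of the other libraries 0.32) and the immune cell list by 0.89 (SD 0.41). Such unlike rises argue against less muscle RNA as the only change in this library. Less muscle RNA alongside another change stays open. Adipose tissue in the sample of this 1 pig is a candidate explanation, with SCD at 6487 CPM (54.4 to 614 in the others), FASN at 3791 CPM (40.8 to 196) and ADIPOQ at 961 CPM (0.64 to 64.4). Of the 27 adipocyte markers tested, 23 were counted in all 25 libraries and 1 is also in the liver list, so muscle samples hold most of them at some level. An effect of the diet in the other 8 pigs stays open, since their adipocyte mean differed from the control by 0.06 log2 CPM (95% interval -0.32 to 0.44, exact permutation p = 0.737).

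The lower oxidative phosphorylation list at 10000 IU/kg and the higher vitamin D list at 5000 IU/kg could follow from libraries with a low share of assigned reads. With this share as a covariate the difference from the control went from -0.37 to -0.19 log2 CPM for oxidative phosphorylation (95% interval -0.42 to 0.03) and from 0.36 to 0.21 for the vitamin D list (-0.01 to 0.43). These intervals hold both 0 and the unadjusted difference, and camera with the preset correlation passed the oxidative phosphorylation list (adjusted p = 6.39e-06, at a median of -0.16 from -0.31) but not the vitamin D list (0.382), and with an estimated correlation neither passed even without the covariate (0.33 and 0.91), so library quality and diet cannot be told apart here. Between the doses, D10000 had the higher mean share (53.5% against 51.8% in D5000), yet its oxidative phosphorylation list was lower. That median was -0.21, and -0.26 with the share as a covariate (camera with the preset correlation, adjusted p = 2.3e-11). With an estimated correlation and no covariate, this contrast had an adjusted p of 0.773. Without the 2 members that it shares with the liver list, the vitamin D list had a median of 0.33 with 12 of 15 genes higher (adjusted p = 0.0625). With liver transcripts as a covariate, the full vitamin D list had a median of 0.03 (adjusted p = 0.484), from 0.38 (adjusted p = 0.0356). A part of this drop is built in, since the 2 shared genes belong to both lists. A part of liver RNA in the vitamin D list stays open. The diet itself stays open for oxidative phosphorylation (list mean -0.37 log2 CPM from the control, 95% interval -0.84 to 0.10, exact permutation p = 0.117), as do litter and sex, which were not tested.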

How the results depend on the processing

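The alternatives chosen after seeing the data were the 5 doubtful libraries left out, the covariates for liver transcripts, adipocyte markers and assigned reads, the term for the APOC3 to ALB ratio, and the vitamin D list without liver genes. The counts of genes past the threshold were 0 under 13 or 14 alternatives per comparison (edgeR, DESeq2 and limma, from 135 to 2180 genes at an unadjusted p under 0.05) and with each of the 25 libraries left out, except 1 gene between the doses with voom quality weights and 2 over the 3 diets with robust=FALSE. Of the 10 measures of library makeup, 0 passed under 2 alternatives or with any 1 library left out. The number of lists past camera moved more, in the order 5000 against control, 10000 against control, 10000 against 5000 and trend (2, 11, 5 and 11). It was 0, 0, 0 and 0 with an estimated correlation and with fry. Leaving out 1 library gave 0 to 6, 5 to 12, 0 to 7 and 5 to 12 lists. For 5000 against control it was 0 without control replicate 10 or 16 or D5000 replicate 29, and 1 without control replicate 9 or D5000 replicate 18. It was 6 without control replicate 3, 5 without control replicate 23 or D5000 replicate 6, and 4 without D5000 replicate 24 or 25. For 10000 against control and for the trend it was 5 without D10000 replicate 27. Between the doses it was 0 without D10000 replicate 2, 2 without D10000 replicate 27, and 3 without D5000 replicate 5 or 15 or D10000 replicate 21. Without the 5 doubtful libraries, none of them a control, it was 2 in each contrast. At 5000 IU/kg these were slow-twitch and immediate-early genes, both higher, in place of the fast-twitch and vitamin D lists, and the share of assigned reads as a covariate gave the same pair. That covariate left 7 lists for 10000 against control and 7 for the trend. Adipocyte markers as a covariate left 6, 2 and 5 lists for 10000 against control, between the doses and for the trend. This covariate is taken from the adipocyte list itself, so the end of the adipocyte calls under it was built in. For 5000 against control, 0 lists were left with no filter on low counts and with the vitamin D list without liver genes, and between the doses 3 were left with 1 surrogate variable. The other counts stayed within 1.5 times, but not always with the same lists. With liver transcripts as a covariate, 0 of the 2 lists were the same for 5000 against control and 3 of the 5 between the doses, where the adipocyte and extracellular matrix calls ended, and with 1 surrogate variable 1 of the 2 was the same for 5000 against control, where the vitamin D call ended. With no filter 16486 genes were tested, and leaving out libraries gives fewer samples; otherwise the cause was not tested. The correlation of the fold changes of both doses was 0.453 to 0.462 with RLE, no filter or a prior count of 2, and 0.0871 with the controls split 4 and 4, which removes the shared libraries. Of 2200 values of named genes under alternatives, 49 had the opposite sign, for 19 of 58 values, and none of the 58 was a call to begin with. A covariate of Y-linked genes was not run, because the 1 such gene tested had counts in every library. With these group sizes, simulated changes were called in 0% to 4% of genes at a fold of 1.5, in 10% to 12% at a fold of 2 and in 72% to 88% at a fold of 8. These rates come from independent genes without an outlying library.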

Other observations

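The tests on liver and lung transcripts were chosen after their genes had been seen in the libraries, and the splits of the libraries were set down before their results were seen.

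Muscle samples held transcripts of organs other than muscle. Surfactant and airway genes of the lung were counted at low levels. SFTPC had 3078 counts in 23 libraries, with a maximum of 829 in D10000 replicate 13, and CLDN18 had 1998 counts in 21 libraries. SLC34A2 had 1774 counts in 20 libraries and SFTPD 1645 counts in 19, and SCGB1A1 and SCGB3A1 had 457 counts in 17 and 591 in 12. D10000 replicate 13 had the highest count of 5 of these 6 genes, and control replicate 9 that of SFTPD (350 counts).

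Liver transcripts were present at 0.706% to 6.82% of counts (median 1.92%), with ALB at 11361 to 103105 counts. RNA from liver is a candidate source, since the 52 liver genes rose and fell together across libraries within diets, with a median pairwise correlation of 0.822 against 0.0638 in the middle of 10000 random gene sets of the same level and 0.291 in the highest. Of these genes 51 were counted in all libraries and 3 are in other lists (CYP27A1, GC and RBP4). The random sets were matched on level only, and the liver list fell with the share of assigned reads (r = -0.740). Other genes that follow this share would also rise and fall together, so the correlation by itself does not single out liver RNA. The counts of APOC3 argue against 1 common liver source for all libraries, because their ratio to ALB differed 26.3-fold, from 0.00992 (95% interval 0.00874 to 0.0112) in D5000 replicate 6 to 0.261 (0.256 to 0.266) in D5000 replicate 24, while the ratio of FGB to ALB differed 2.2-fold (0.235 to 0.518). An effect of the diets stays open (permutation p = 0.419, D5000 minus control -0.28 to 1.24 log2 CPM), and where such RNA entered was not tested.

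Regrouping the libraries at random showed how many lists pass camera with the preset correlation when groups ignore the diet. The median of the other splits was 6 lists in each of the 4 list comparisons. The real counts of 2 and 5 lists lay under that median. Among 100 splits into 8, 8 and 9 libraries, the real one included, 96 gave at least the 2 lists of 5000 IU/kg against control (highest other 13) and 63 at least the 5 lists between the doses (highest other 14). For 10000 IU/kg against control 12 splits gave at least 11 lists (highest other 12), and for the trend 13 did (highest other 12), so chance could not be excluded for any of the 4 list counts. The real count of genes was 0 in each of the 5 gene comparisons, which all 100 splits reach whatever the data, so these counts decide nothing about chance. The highest other counts were 449 genes for 5000 IU/kg against control, 8 for 10000 IU/kg against control, 1 between the doses, 2 over the 3 diets and 1 for the trend. The split with 449 genes points to a structure of the samples: it had the widest gap in the share of assigned reads of all splits, 45.1% against 61.1%. At an unadjusted p under 0.05 the real counts of 371, 263, 323, 292 and 291 genes lay under the medians of the other splits (453, 442, 453, 460 and 470).

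The first principal component of the libraries held 19.1% of the variance and had r = -0.942 with the share of assigned reads across the 25 libraries, described here without a test.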
